A study of Mus musculus with 36 samples.

How the data were processed

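The values were the authors' deposited expression table of 36 mouse Affymetrix arrays, in log2 intensity, made with the robust multi-array average (RMA) in the affy package per the submitters' processing notes. The notes do not name a later adjustment. In the values, however, the coefficients of hybridisation batch, scan batch and tumour cell line were below 1e-6 in 100% of the 45141 probe sets once diet and shRNA were in the model, against 0.00222% of probe sets without diet and shRNA. The deposited values had therefore been adjusted for these 3 labelled factors with diet and shRNA kept, and they were not adjusted again before the fit. The experiment term of the fit below coincides with hybridisation batch. Array medians lay between 5.98 and 6.04 log2. No raw intensity files were used.

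The annotation gave a gene for 29449 probe sets, and 551 of these carried several genes and were left out. Of the remaining 28898, 28689 were matched to a gene identifier. The other 15692 of the 45141 probe sets had no gene, and 104 of all probe sets were array controls. Probe sets without a listed gene were not tested. For the 7180 genes with several probe sets, the probe set with the highest mean over all arrays stood for the gene. Of 17097 genes, the 25% with the lowest mean were left out, those under 5.19 log2, which left 12823.

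The labels name 11 groups, each 1 biological replicate measured on 3 or 4 arrays labelled as technical replicates. Arrays of a group were averaged, and limma 3.58.1 in R 4.3.3 was fitted to the 11 averages with condition and experiment as fixed terms. The fit had 4 residual degrees of freedom and 2.70 prior degrees of freedom. The 7 contrasts were palmitate over control diet in non-targeting tumours, the same in shCD36 tumours, shCD36 over non-targeting on each of both diets, the difference of the palmitate effect between shRNAs, oleate over control and palmitate over oleate. Benjamini-Hochberg adjusted p under 0.05 was called over all genes of a contrast. Because the first VDH15 experiment enters the fit with the non-targeting groups only, estimates that involve shCD36 or oleate can differ from a plain difference within their experiments, in some lists also in direction. A second set of limma fits took the arrays of 1 experiment at a time; its error covers only the spread among arrays labelled technical replicates. Whether the arrays of a group came from 1 RNA sample, 1 tumour or several mice is not stated. Agreement counted genes called in the same direction in every experiment. Shared use of arrays between contrasts was weighed with 100 simulated data sets without any effect. Group labels were exchanged among arrays or averages in every possible split, or in 100 random ones, and the calls were counted again.

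Gene lists were fixed before the data were examined and were written from general knowledge. The 35 lists are Schwann cell and glial identity, myelin genes, Schwann cell repair and injury response, perineuronal net and proteoglycan matrix, galanin and neuropeptide system, neurotrophic factors and receptors, axon guidance cues and receptors, neuron and synapse genes, fibroblast genes, pericyte and smooth muscle genes, endothelial genes, macrophage and myeloid genes, neutrophil genes, keratinocyte and epithelial genes, skeletal muscle genes, muscle satellite cell genes, adipocyte genes, red blood cell genes, collagens, matrix glycoproteins and laminins, matrix proteases and inhibitors, TGF-beta response, inflammatory cytokines and chemokines, interferon response, antigen presentation, PPAR targets and fatty acid oxidation, fatty acid synthesis and desaturation, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, cell cycle and proliferation, immediate early and heat shock genes, endoplasmic reticulum stress, ribosomal proteins, and neural crest and epithelial-mesenchymal transition regulators. Some lists share members: the fibroblast list shares 2 genes with the collagens. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists of a contrast. Camera with an estimated correlation and fry were the alternatives; values of fry depend slightly on the order of the samples in the model. Members were also adjusted over the list alone.

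Genes were named by a rule fixed before the data were examined. For palmitate over control in non-targeting tumours these were the 12 highest and 12 lowest log2 fold changes among called genes with 1 sign in all 3 experiments. For other contrasts they were 6 and 6, filled up where too few passed with the smallest unadjusted p of that sign in every experiment. For agreement they were up to 10 per direction, ranked by the smallest absolute log2 fold change among experiments, and for each list up to 4 members with the smallest unadjusted p. Predicted genes without an established name were passed over. Cd36, Gal and Galr1 to Galr3 were always read.

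Alternatives fixed before the data were examined were duplicateCorrelation on all 36 arrays, no experiment term, no filter or a filter of 50%, quantile normalization, median centring, the mean of all probe sets, eBayes with trend and robust, only the groups of the contrast, each experiment or array left out, the technical replicate number as a block, scan batch as a block or each scan batch alone, and an absolute log2 fold change of at least 1. Leaving out 3 arrays that stood apart was chosen after seeing the data. Cell-type comparisons used members with a mean of at least 7 log2 and permutation tests with 100000 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Error values are standard errors of the fit unless named otherwise.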

Results

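Gene expression was measured on 36 mouse arrays in the stromal cells labelled neural fraction, taken from human oral carcinomas growing in the mouth of immunodeficient NSG mice. The tumours grew from SCC25, an established human oral carcinoma line, or from cells labelled VDH15, and carried either a non-targeting shRNA or an shRNA against CD36, a fatty acid receptor. Mice received a control diet, a diet rich in palmitic acid or a diet rich in oleic acid. The arrays fell into 11 groups of 3 or 4 technical replicates, each group being 1 labelled biological replicate. The first VDH15 experiment held non-targeting tumours on control, palmitate and oleate diets with 4 arrays each. The SCC25 experiment and the second VDH15 experiment each held both shRNAs on control and palmitate diets with 3 arrays per group. Comparisons therefore rest on n = 3 biological replicates for palmitate over control in non-targeting tumours, n = 2 for every comparison with shCD36 and n = 1 for oleate, and the number of arrays limits the precision. The shRNA was in the human tumour cells, so mouse Cd36 on these arrays does not check the labels. Keratinocyte and epithelial genes had a median level of 10.7 log2 over all arrays and fibroblast genes 9.36 log2. Schwann cell and glial identity genes had 6.53, neuron and synapse genes 5.61 and myelin genes 5.56 log2. The purity of the fraction was not tested. The first principal component held 38.7% of the variance of the 36 arrays and the second held 13.3%. On the first component 3 arrays stood apart, with scores of 81.3 and 75.1 for replicates 1 and 2 of the palmitate group in the first VDH15 experiment and 60.6 for replicate 1 in the second. The other palmitate arrays of non-targeting tumours scored between 21.1 and 31.8.

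**Figure D1:**
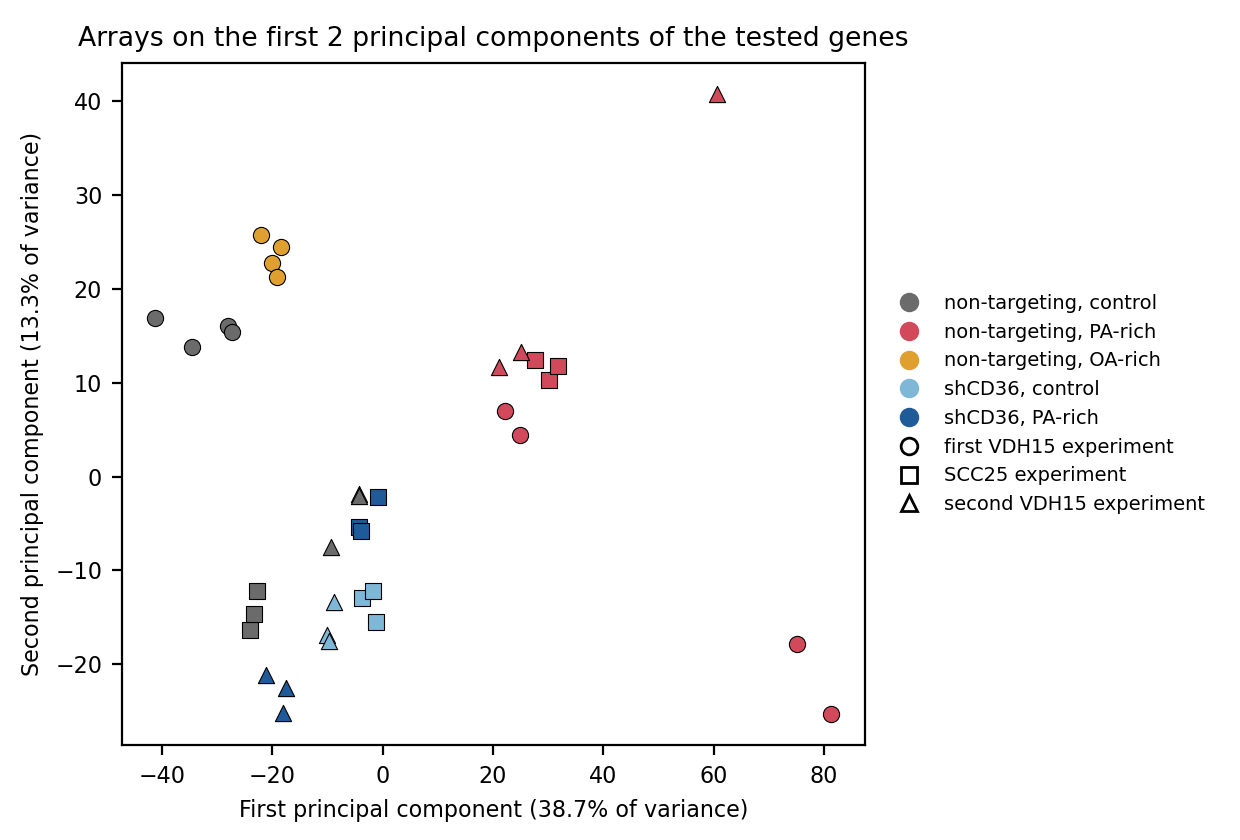
Scores of the 36 arrays on the first component (38.7% of the variance) and the second (13.3%), each point an array, by group and experiment. The 3 arrays at 81.3, 75.1 and 60.6 belong to palmitate groups of non-targeting tumours.

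The first comparison asked what a palmitate-rich diet of the host changed in the neural fraction of tumours that carried the non-targeting shRNA. It called 887 of 12823 genes, 468 higher and 419 lower, and all 887 had 1 sign in the 3 experiments. Of the 12 called genes with the largest rise, 6 code for collagens, proteoglycans or a cross-linking enzyme of the matrix. The collagen gene Col6a3 (1424131_PM_at) rose by 2.61 ± 0.43 log2 (SE, n = 3, adjusted p = 0.0276), from a mean of 9.21 to 11.8 log2. Lox (1448228_PM_at), whose product cross-links collagen and elastin, rose 4.42-fold, by 2.15 ± 0.30 log2 (adjusted p = 0.0199). Alongside rose the collagen genes Col5a3 (2.08 ± 0.27; 1419703_PM_at) and Col5a2 (2.05 ± 0.35; 1422437_PM_at) and the small proteoglycans Lum (1.94 ± 0.38; 1423607_PM_at) and Bgn (1.94 ± 0.41; 1448323_PM_a_at). The thyroid hormone deiodinase Dio2 (2.07 ± 0.27; 1418937_PM_at), Cyp1b1 (2.00 ± 0.35) and the transcription factor Zfp521 (1.93 ± 0.37) were also among the 12 highest. So were Fgl2 (1.89 ± 0.41), the adhesion gene Nectin3 (1.88 ± 0.37) and the macrophage mannose receptor Mrc1 (1.85 ± 0.41). Genes known from differentiated epithelium were among the called genes with the largest fall. The ceramidase Acer1 (1439183_PM_at) fell by 2.78 ± 0.17 log2 (adjusted p = 0.00593) and Ly6g6c (1422749_PM_at) by 2.86 ± 0.40 log2 (adjusted p = 0.0198). The cornified envelope genes Sprr1a (−2.11 ± 0.29), Sprr1b (−1.94 ± 0.31) and Cnfn (−1.92 ± 0.37) fell, as did the barrier genes Alox12b (−2.16 ± 0.35) and Spink5 (−1.95 ± 0.22) and the keratins Krt84 (−2.32 ± 0.48) and Krt4 (−1.95 ± 0.34). Gsta2 (−2.12 ± 0.27), Psapl1 (−2.01 ± 0.15) and the protease inhibitor Serpinb3a (−1.96 ± 0.40) completed the 12 lowest called genes when the provisional names 2310011E23Rik and Gm94 are left out. Fold changes of 434 genes exceeded 1 log2 in either direction.

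Across the fixed lists, 11 moved up and 3 moved down with the palmitate diet. Fibroblast genes had a median of 1.44 log2 over 17 genes (adjusted p = 4.54e-10, and 0.227 with an estimated correlation), with medians of 0.84 to 1.73 in single experiments. Without the 3 arrays that stood apart the fibroblast median was 1.11, the endothelial 1.12 and the collagen median 0.87 log2, and all 3 lists were still called. Of these 17, 11 rose over all genes and 14 adjusted over the list alone, among them Postn (1.56 ± 0.19), Serpinf1 (1.78 ± 0.23) and S100a4 (0.89 ± 0.11). Endothelial genes were higher in 21 of 21 members with a median of 1.26 log2 (adjusted p = 1.02e-11, and 0.409 with an estimated correlation). Of them 6 rose over all genes and 18 adjusted over the list alone, including Sox18 (0.97 ± 0.14), Plvap (1.08 ± 0.19), Vwf (1.26 ± 0.24) and Ptprb (1.52 ± 0.32). Collagens had a median of 1.15 log2 over 23 genes (adjusted p = 2.74e-07, and 0.326 with an estimated correlation). Over all genes 7 rose, including Col6a2 (1.24 ± 0.12), Col5a1 (1.84 ± 0.20) and Col6a1 (1.15 ± 0.18); adjusted over the list alone 16 rose and 2 fell. Matrix glycoproteins and laminins (median 0.61, adjusted p = 8.89e-10, 0.205 with an estimated correlation) rose in 7 of 23 members and in 16 adjusted over the list alone, with Thbs2 at 1.65 ± 0.23, Eln at 1.12 ± 0.16 and Hspg2 at 0.96 ± 0.15. Matrix proteases and inhibitors (median 0.74, adjusted p = 1.01e-09, 0.133 with an estimated correlation) rose in 7 of 23 members and in 18 adjusted over the list alone. The metalloproteinase Mmp19 (1.69 ± 0.15), the disintegrin Adam12 (1.81 ± 0.19) and the inhibitors Timp1 (1.73 ± 0.21) and Timp2 (1.39 ± 0.22) were among them. In the perineuronal net and proteoglycan matrix list the median was 0.13 (adjusted p = 0.0083, 0.227 with an estimated correlation), 4 of 17 genes rose and 6 adjusted over the list alone, including Vcan (1.45 ± 0.16), Chsy1 (0.55 ± 0.09) and Tnc (0.61 ± 0.13). Without the 3 arrays that stood apart its median was 0.03, and the list was still called. The TGF-beta response list (median 0.17, adjusted p = 0.00447, 0.33 with an estimated correlation) had 4 genes that rose of 19: Ccn2 (1.22 ± 0.13), Tgfb1 (0.85 ± 0.17), Tgfb3 (1.44 ± 0.31) and Tgfb2 (0.60 ± 0.13). Adjusted over the list alone 4 rose and 1 fell. Neural crest and epithelial-mesenchymal transition regulators had a median of 0.29 (adjusted p = 0.00114, 0.205 with an estimated correlation). The mesenchymal transcription factors Prrx1 (1.65 ± 0.13), Zeb2 (0.99 ± 0.14) and Twist2 (0.90 ± 0.17) rose among 17 genes, and Cdh11 (1.30 ± 0.29) did not pass. Adjusted over the list alone, 10 rose and 1 fell. Of the pericyte and smooth muscle genes (median 0.49, adjusted p = 0.0134, 0.595 with an estimated correlation), only Mcam (0.88 ± 0.14) rose of 14, over all genes and over the list alone. The mural cell genes Pdgfrb (0.75 ± 0.21), Acta2 (0.65 ± 0.21) and Ndufa4l2 (−0.51 ± 0.17) did not pass. Without biological replicate 2, the SCC25 experiment, the adjusted p of the pericyte list was 0.304.

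The macrophage and inflammatory lists moved up, and the keratinocyte, cholesterol synthesis and oxidative phosphorylation lists moved down. Macrophage and myeloid genes were higher in 17 of 18 members (median 0.47, adjusted p = 2.74e-07, 0.447 with an estimated correlation), with medians of 1.07, 0.07 and 0.42 in the first VDH15, SCC25 and second VDH15 experiments. The lipopolysaccharide co-receptor Cd14 (1.24 ± 0.14) and Mrc1 rose, and 8 genes rose adjusted over the list alone. The lysosomal genes Lyz2 (1.84 ± 0.42) and Ctss (1.76 ± 0.45) did not pass over all genes. Inflammatory cytokines and chemokines had a median of 0.35 over 29 genes (adjusted p = 2.97e-05, 0.246 with an estimated correlation). Of these 6 rose, including Cxcl9 (0.95 ± 0.09), Cxcl5 (1.72 ± 0.25) and Lif (0.70 ± 0.12), and Ccl20 (−0.89 ± 0.13) fell; adjusted over the list alone 12 rose and 1 fell. Keratinocyte and epithelial genes were lower in 19 of 20 members, with a median of −0.39 (adjusted p = 6.29e-05, 0.595 with an estimated correlation) and −0.72 to −0.13 in single experiments. Without the 3 arrays that stood apart the median was −0.19 (adjusted p = 0.0014), and −0.25 in place of −0.72 in the first VDH15 experiment. The simple-epithelial claudin Cldn4 (−1.15 ± 0.17) and the mucosal keratins Krt4 and Krt13 (−1.23 ± 0.26) fell, and 9 genes fell adjusted over the list alone. The stress keratin Krt6b (−1.53 ± 0.37) did not pass over all genes. Cholesterol synthesis genes (median −0.17, adjusted p = 0.0301, 0.542 with an estimated correlation) fell in 2 of 18 members, Fdft1 (−0.75 ± 0.07) and Dhcr7 (−0.38 ± 0.09), and in 5 adjusted over the list alone, where 1 rose. Sqle (−0.39 ± 0.09) and Sc5d (−0.53 ± 0.13) did not pass over all genes. Without the SCC25 experiment the adjusted p of this list was 0.326. Oxidative phosphorylation genes were lower in 28 of 30 members with a median of −0.12 (adjusted p = 0.00619, 0.729 with an estimated correlation), and none of them passed over all genes or over the list alone. Uqcrfs1, a complex III subunit, had the smallest p at −0.25 ± 0.08. Without biological replicate 1, the first VDH15 experiment, the adjusted p was 0.168.

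The remaining 21 lists were not called for palmitate over control, and single members moved within them. In the Schwann cell and glial identity list (median −0.03, adjusted p = 0.932) the glial sodium channel Scn7a (1.31 ± 0.16) and Ncam1 (0.84 ± 0.17) rose and L1cam (−0.57 ± 0.06) fell of 17. Erbb3, the neuregulin receptor of Schwann cells, stood at −0.82 ± 0.23 without passing. Over the list alone, 2 rose and 2 fell. Of 8 myelin genes (median −0.09, adjusted p = 0.868) none passed over all genes, with Dhh at 0.36 ± 0.09, Drp2 at −0.13 ± 0.07 and Mbp at −0.09 ± 0.07. In this list 1 gene rose adjusted over the list alone. Schwann cell repair and injury response (median −0.03, adjusted p = 0.536) had 3 of 19 genes that rose in both adjustments, the cytokines Lif and Il6 (1.39 ± 0.26) and the matrix gene Tnc. The growth cone gene Gap43 (1.00 ± 0.32) did not pass. In the galanin and neuropeptide system (12 genes, median 0.09, adjusted p = 0.207) 0 genes passed in either adjustment. The receptor gene Calcrl (1.67 ± 0.42), Penk (0.61 ± 0.19), Npy (0.71 ± 0.35) and Tacr1 (0.17 ± 0.08) had the smallest p. The neuropeptide gene Gal (1460668_PM_at) stood at 0.06 ± 0.08, Galr1 at −0.07 ± 0.07 and Galr3 at −0.08 ± 0.06, and Galr2, at −0.09 ± 0.07, lay below the expression filter. Neurotrophic factors and receptors (median 0.04, adjusted p = 0.248) included Igf1 (1.45 ± 0.28) and Lifr (0.31 ± 0.06) among 3 of 18 that rose, 4 adjusted over the list alone, and Ret (0.46 ± 0.12) did not pass. Of 34 axon guidance genes (median 0.03, adjusted p = 0.592) the semaphorins Sema4d (−0.96 ± 0.14), Sema4a (−0.77 ± 0.13) and Sema5a (−0.59 ± 0.12) and the ephrin Efnb1 (−0.45 ± 0.10) fell. Over this list alone 7 rose and 8 fell. Neuron and synapse genes (median −0.01, adjusted p = 0.932) had 2 of 16 that fell in both adjustments, the cytoskeletal genes Tubb3 (−1.16 ± 0.14) and Map2 (−0.69 ± 0.10). Stmn2, which marks regrowing neurons, stood at 0.23 ± 0.08. Hypoxia and glycolysis (median −0.02, adjusted p = 0.868) had 3 of 24 that fell, Egln3 (−0.88 ± 0.11), Pdk1 (−0.38 ± 0.06) and Hk2 (−0.57 ± 0.10), with 1 that rose and 3 that fell adjusted over the list alone. Of 26 immediate early and heat shock genes (median −0.11, adjusted p = 0.0688) Klf2 (0.69 ± 0.09) rose and Hspa1b (−0.77 ± 0.12) and Ier2 (−0.54 ± 0.09) fell, and 1 rose and 4 fell adjusted over the list alone. Fatty acid synthesis and desaturation (19 genes, median −0.09, adjusted p = 0.9) held Fads3 (0.72 ± 0.13), which rose, and Acss2 (−0.83 ± 0.18), which fell; adjusted over the list alone 3 rose and 4 fell.

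In the lists without a called member, PPAR targets and fatty acid oxidation (25 genes) had a median of −0.16 and an adjusted p of 0.151. The mitochondrial fatty acid genes Cpt2 (−0.53 ± 0.12) and Cpt1a (−0.46 ± 0.11), the carrier Fabp5 (−0.39 ± 0.09) and Angptl4 (0.71 ± 0.17) were nearest to passing, and 3 rose and 7 fell adjusted over the list alone. Cd36, the fatty acid receptor itself (1423166_PM_at), stood at 0.36 ± 0.10 (adjusted p = 0.0687) at a low mean level of 5.34 log2. Interferon response genes had a median of 0.01 over 22 genes (adjusted p = 0.38), with Rsad2 at 0.66 ± 0.23 and Oasl2 at −0.48 ± 0.19. Antigen presentation (median 0.04, adjusted p = 0.207; Cd74 0.55 ± 0.16) and neutrophil genes (0.12, 0.0847; Lcn2 0.97 ± 0.46) held no gene that passed. Adipocyte genes (0.15, 0.0799; Fabp4 1.44 ± 0.46) and red blood cell genes (0.13, 0.361; Alas2 1.26 ± 0.65) held none either. The same held for skeletal muscle genes (median −0.03, adjusted p = 0.743; Acta1 −0.20 ± 0.09) and muscle satellite cell genes (−0.03, 0.921; Vcam1 0.92 ± 0.22 and Sdc4 −0.34 ± 0.08), of which 1 rose and 1 fell adjusted over the list alone. Cell cycle and proliferation (median −0.04, adjusted p = 0.918; Mcm6 0.44 ± 0.11) ranged from −0.40 to 0.14 between experiments. Endoplasmic reticulum stress (0.05, 0.0959; Pdia6 0.24 ± 0.08) and ribosomal proteins (−0.06, 0.152; Rpl13 0.15 ± 0.06, and −0.00228 as the mean of all its probe sets) had no gene that passed.

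The test for these genes was limma on the biological replicate averages. Without biological replicate 1, 224 genes were called, of which 192 were among the 887, and 0 were called without biological replicate 2 or without biological replicate 3. The fold changes of these 3 fits had r = 0.93, 0.96 and 0.98 with those of all replicates. They share averages with the full fit, so a high r is partly built in. The fits without biological replicate 2 or 3 also had fewer residual degrees of freedom than the fit without biological replicate 1. Their counts therefore do not show which experiments carry the calls. Without the 3 arrays that stood apart, 599 genes were called and 531 of these were shared. DuplicateCorrelation over all arrays called 3052 genes, a fit without the experiment term 3001 and a fit of the groups of this contrast alone 34. DuplicateCorrelation takes arrays labelled technical replicates as units, with 1 consensus correlation of 0.295 within groups. Its counts add no biological replicates. Exchanging the diet labels among the 6 averages gave at most 1 called gene in the other 9 splits, whereas the camera counts in them were 6 to 15 lists, against 14 for the real labels. With an estimated correlation none of the 14 lists was called, with a smallest adjusted p of 0.133. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, called 9 of the 14. Within the first VDH15 experiment the 2 scan batches gave fibroblast medians of 0.90 and 1.01, endothelial medians of 1.44 and 1.20 and keratinocyte medians of −0.86 and −0.65.

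**Figure D2:**
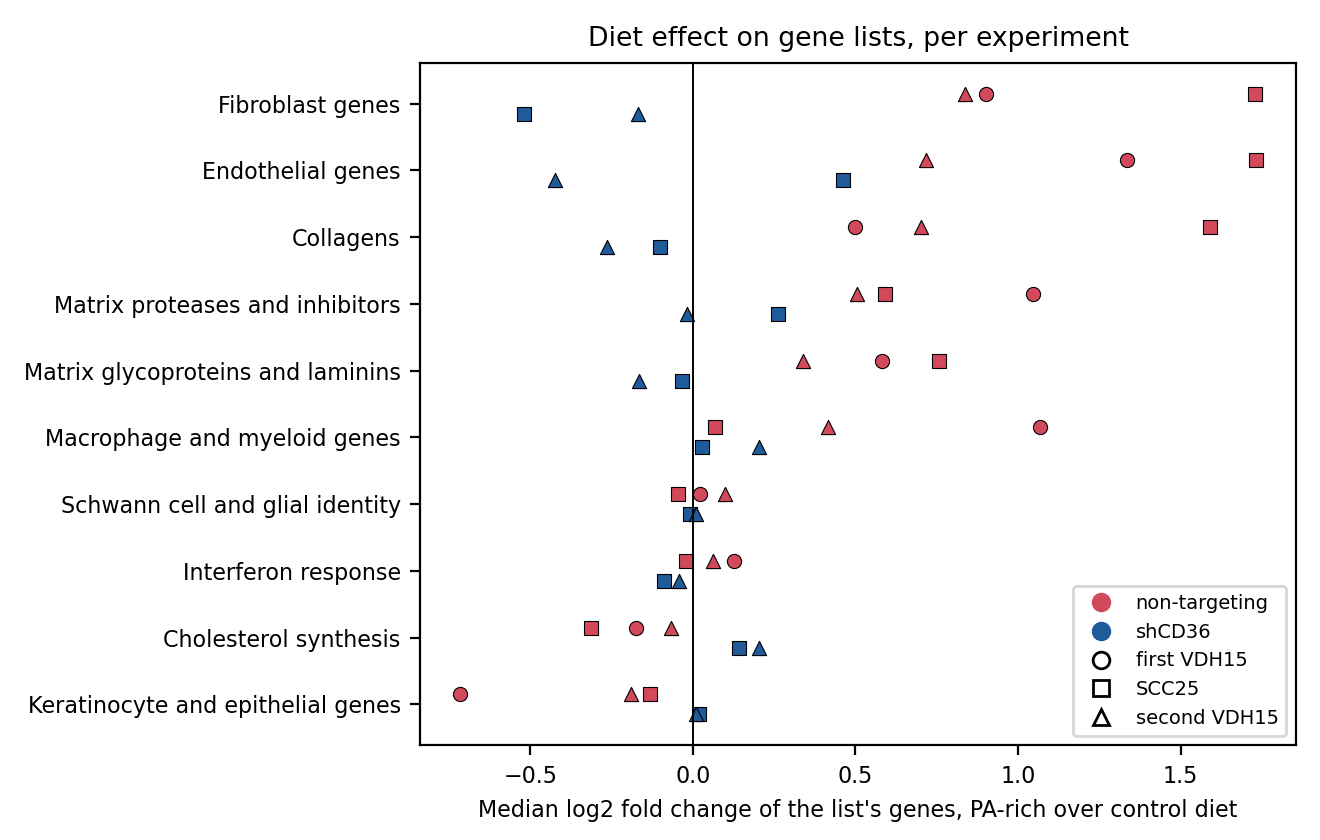
Median log2 fold change of palmitate over control diet for 10 lists, each point 1 experiment, in non-targeting and shCD36 tumours. Fibroblast medians lay between 0.84 and 1.73 log2 in non-targeting tumours.

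The experiments were also fitted one at a time to ask which palmitate responses recur across tumours of both cell sources; their error covers only the spread among arrays labelled technical replicates. Palmitate over control called 5939 genes in the first VDH15 experiment, 2454 in SCC25 and 1846 in the second VDH15 experiment. In all 3 experiments 513 genes were called higher and 380 lower, where independence predicts 17.8 and 22.9, and 201 genes were called in opposite directions. This prediction, here and below, takes genes as moving separately. Genes that move together by chance in single replicates can exceed it without a recurring effect of the diet. The genes that rose in every experiment with the largest smallest change included the matrix genes Olfml3, Pxdn and Thbs2, the proteinases Adam12, Ctsk and Mmp19, the proteoglycan Srgn, and Dio2 and Lox. Ctsk, a collagen-degrading cathepsin, stood at 1.64 ± 0.12 log2 in the combined fit and Olfml3 at 1.85 ± 0.24. Reln, which codes for a secreted guidance protein, was in this group although it did not pass in the combined fit (1.75 ± 0.60, adjusted p = 0.123). Those that fell in every experiment included Spink5, Pla2g4f (−1.86 ± 0.14), Aldh3b2 (−1.72 ± 0.15), Gsdmc (−1.77 ± 0.17), Homer2 (−1.76 ± 0.12), Calm4 (−1.64 ± 0.18), Krtdap (−1.72 ± 0.18), Cyp4f39 (−1.45 ± 0.14), Sult2b1 (−1.43 ± 0.10) and Rdh12 (−1.41 ± 0.13). Sizes differed: Acer1 stood at −3.07, −3.06 and −2.22 log2 in the first VDH15, SCC25 and second VDH15 experiments. Col6a3 stood at 1.08, 3.67 and 3.09 log2. Across genes, which are not independent replicates, the fold changes of SCC25 and the second VDH15 experiment had r = 0.70 and rho = 0.60; the first VDH15 experiment gave r = 0.61 (rho = 0.47) with SCC25 and r = 0.57 (rho = 0.42) with the second, among 7 such correlations computed. In the second VDH15 experiment 757 genes were called without replicate 1 of the non-targeting control group, 1123 without replicate 2 and 1230 without replicate 3. Each scan batch of the first VDH15 experiment alone, with 2 arrays per group, called 1052 and 1278 genes. With an absolute log2 fold change of at least 1, 79 genes were called in all 3 experiments.

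**Figure D3:**
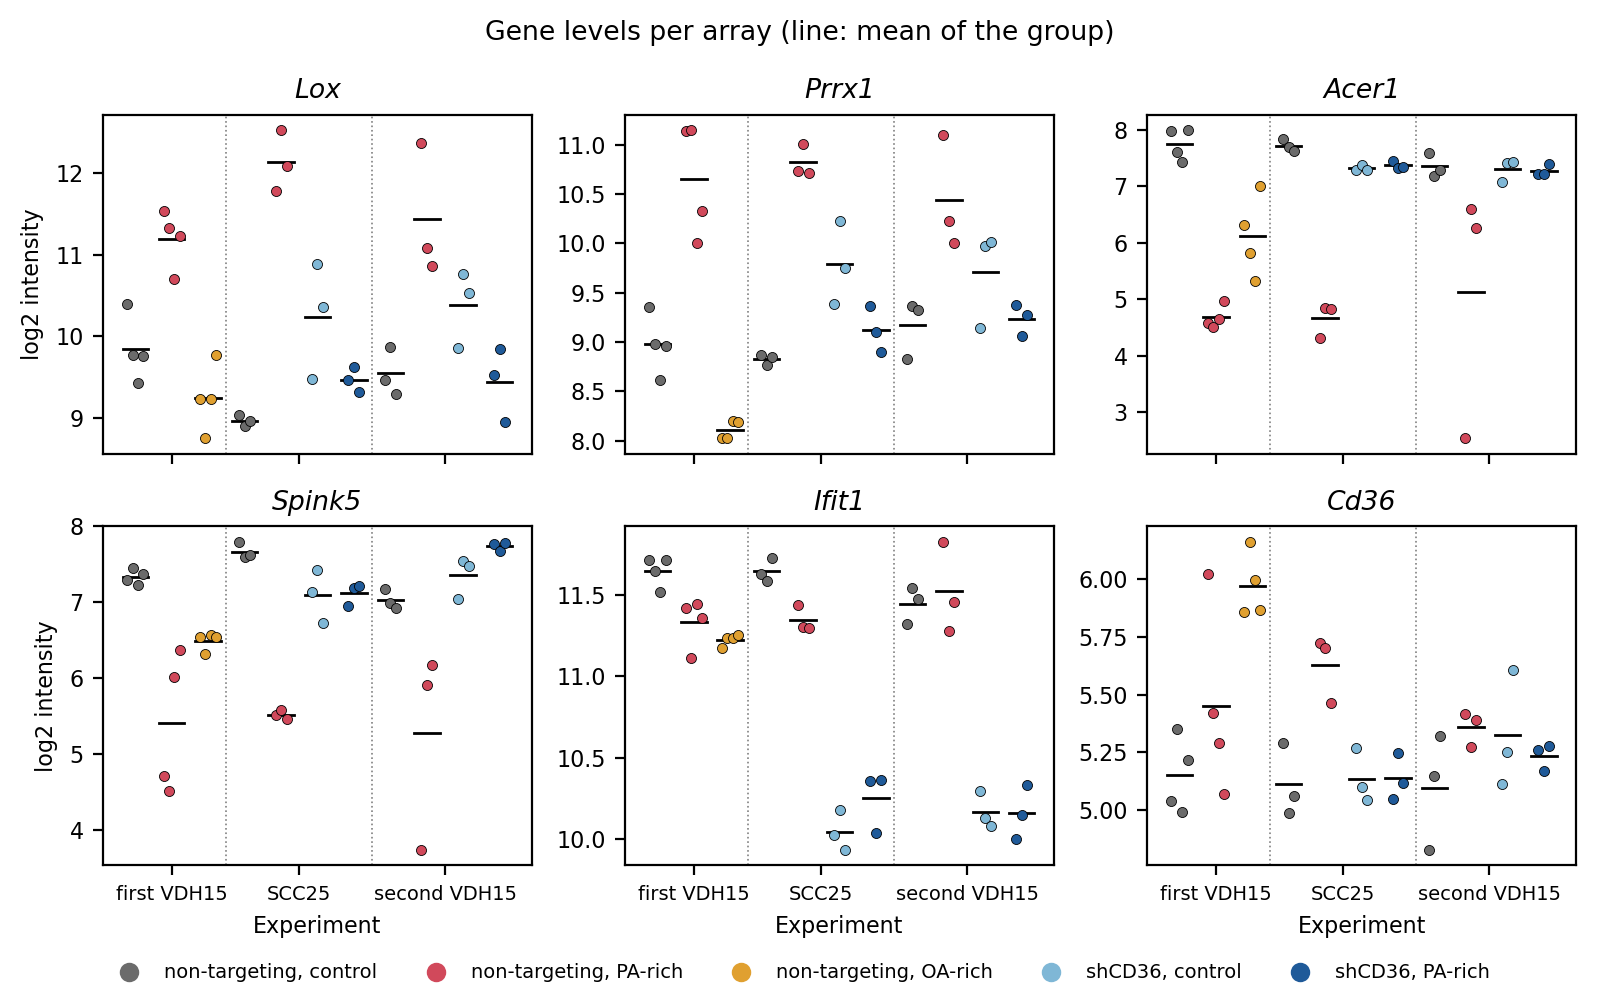
Levels in log2 intensity of Lox, Prrx1, Acer1, Spink5, Ifit1 and Cd36 per array, with a line at each group mean, in the 3 experiments. Acer1 had a mean of 7.61 log2 in non-targeting tumours on control diet and 4.83 log2 on palmitate.

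The same diet comparison in tumours with shCD36 asked whether the palmitate response of the stroma remained when tumour cells carried the shRNA against CD36. It called 0 genes with limma, 282 genes had an unadjusted p under 0.05 where chance predicts 641, and duplicateCorrelation on all arrays called 7. The error of the fit is pooled over all groups and may be too large for this contrast. A count below chance is therefore no evidence that the response was absent. Recovery was simulated for shCD36 over non-targeting on palmitate, also n = 2. Of 200 genes picked at random, 0 were recovered at a change of 0.5 log2 and 184 at 1 log2. For palmitate in non-targeting tumours these were 76 and 185. The simulation drew the noise of each gene independently, and genes that change in the real data can vary more. For shCD36 over non-targeting on palmitate, 357 real genes exceeded 1 log2 in either direction and 48 were called. Moderate changes, and also changes over 1 log2, could therefore be missed in comparisons with shCD36. The 468 genes that rose in non-targeting tumours, with a median of 0.84 log2 there, had a median of −0.07 in shCD36 tumours, and the 419 that fell, with −0.65 there, had 0.03. Lox stood at 10.3 log2 on control and 9.45 log2 on palmitate in shCD36 tumours, against 9.45 and 11.6 log2 in non-targeting tumours. The genes with the smallest p and 1 sign in both experiments did not pass: the alarmin Il33 (1416200_PM_at) at 1.88 ± 0.24 log2 (n = 2), Serpinb1a (1.05 ± 0.18), Trib3 (0.75 ± 0.13), Cdk5r1 (0.65 ± 0.13), Prelid2 (0.57 ± 0.10) and Il4ra (0.53 ± 0.10). On the lower side were the late cornified envelope genes Lce1b (−1.22 ± 0.17), Lce1a2 (−1.67 ± 0.31) and Lce1d (−1.28 ± 0.27), with Celf2 (−0.52 ± 0.09), Slurp1 (−0.64 ± 0.13) and Fmo2 (−0.69 ± 0.16). In separate fits SCC25 called 816 genes and the second VDH15 experiment 162, of which 18 were higher and 7 lower in both, against 1.97 and 1.90 by independence, and 11 were called in opposite directions. Higher in both were Il33 (1.73 and 2.03), the envelope gene Sprr2a1 (1.66 and 1.63), the interleukin 10 family cytokines Il20 (2.08 and 1.15) and Il24 (1.86 and 0.99), Slfn2 (1.27 and 0.91) and Sox9 (0.99 and 0.67). Lower in both were Rrad (−0.62 and −0.82), Fxyd1 (−0.61 and −0.67) and Celf2 (−0.42 and −0.62). With an absolute log2 fold change of at least 1 these were 3 genes. Across genes the fold changes of both experiments had r = 0.12 (rho = 0.04). The lists on the higher side were cholesterol synthesis (18 of 18 higher, median 0.19, adjusted p = 6.52e-07; Sqle 0.48 ± 0.12), hypoxia and glycolysis (22 of 24, 0.11, 1.18e-06; Egln3 0.38 ± 0.13), macrophage genes (17 of 18, 0.13, 0.0176) and neutrophil genes (9 of 10, 0.15, 0.0176; S100a8 1.48 ± 0.51). With an estimated correlation their adjusted p was 0.37, 0.351, 0.762 and 0.635. On the lower side were fibroblast genes (16 of 17 lower, median −0.53, adjusted p = 6.52e-07; Postn −0.75 ± 0.23), collagens (16 of 23, −0.11, 0.00503), matrix glycoproteins (16 of 23, −0.08, 0.00257; Thbs3 −0.55 ± 0.16) and pericyte genes (11 of 14, −0.13, 0.0116). With an estimated correlation these had 0.603, 0.635, 0.625 and 0.635. So were red blood cell genes (5 of 6, −0.13, 0.0176), cell cycle genes (23 of 31, −0.12, 0.00519) and immediate early genes (21 of 26, −0.05, 0.015), at 0.635, 0.812 and 0.762 with an estimated correlation. Endothelial genes were not called, with 19 of 21 higher in SCC25 (median 0.46) and 0 of 21 higher in the second VDH15 experiment (−0.42). None of the members of called lists passed, and adjusted over the list alone only Il33 and Trib3 rose, both in lists that were not called. No list was called with an estimated correlation (smallest adjusted p = 0.351) or by fry. Without biological replicate 2, 17 lists were called, red blood cell genes turned direction (adjusted p = 0.94) and immediate early genes did not pass (0.114). Without biological replicate 3, the second VDH15 experiment, 5 lists were called. Cell cycle genes then turned direction (0.568), and macrophage and neutrophil genes (0.436), pericyte genes (0.15), immediate early genes (0.076), collagens (0.0596) and matrix glycoproteins (0.0576) did not pass. With no expression filter neutrophil genes had 0.0747. Without single arrays the SCC25 count fell to 512 (shCD36 control replicate 1), 496 (shCD36 control replicate 3) and 541 (shCD36 palmitate replicate 1). Without any 1 of the 6 arrays of the second VDH15 experiment between 20 and 70 genes were called.

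The difference of both palmitate responses, shCD36 minus non-targeting, asked whether CD36 in the tumour cells alters the response of the stroma to the diet. No gene passed with limma, although 2011 genes had an unadjusted p under 0.05; the smallest adjusted p, 0.0516, was shared by Antxr2 (−1.19 ± 0.11; 1426708_PM_at), Acer1 (2.79 ± 0.26), Prrx1 (−2.22 ± 0.21), Rian (−1.58 ± 0.15), Homer2 (1.92 ± 0.19) and Sult2b1 (1.58 ± 0.15). Without the block for experiment 699 genes were called, and with duplicateCorrelation 1052. Both fits have more residual degrees of freedom, from the dropped term or from arrays labelled technical replicates. Others that did not pass were Mmp19 (−2.28 ± 0.24), Ctsk (−1.86 ± 0.20) and Ccn2 (−1.82 ± 0.20) on the lower side. On the higher side were Selenbp2 (1.39 ± 0.16), Rnf144b (1.20 ± 0.13) and L1cam (0.84 ± 0.10). In separate fits the SCC25 experiment called 1992 genes and the second VDH15 experiment 1224. In both, 239 were higher and 353 lower, where independence predicts 41.3 and 51.7, with r = 0.64 (rho = 0.46) across genes, and 175 genes had an absolute log2 fold change of at least 1. Lower in both were Col6a3 (−4.12 and −3.65), Col1a1 (−5.23 and −2.93), Lox (−3.95 and −2.84), Col5a3 (−2.68 and −3.48), Timp1 (−2.69 and −2.46), the pericyte gene Rgs5 (−2.78 and −2.32) and Postn (−2.32 and −2.80). Higher in both were Il33 (2.83 and 2.24), Sprr2a1 (3.66 and 2.22) and Sprr2d (5.19 and 2.09). The lists on the lower side were fibroblast (median −1.93, adjusted p = 2.01e-12, 15 of 17 lower adjusted over the list alone; Postn −2.31 ± 0.30), matrix glycoproteins (−0.77, 4.91e-11, 11 of 23), endothelial (−1.22, 5.28e-10, 3 of 21; Vwf −1.83 ± 0.37), collagens (−1.29, 6.24e-08, 6 of 23) and matrix proteases (−0.55, 7.5e-08, 7 of 23). Their adjusted p with an estimated correlation was 0.181, 0.162, 0.358, 0.282 and 0.162. They also included macrophage (−0.38, 0.00138; Cd14 −1.20 ± 0.22), pericyte (−0.64, 0.00202), neural crest (−0.33, 0.00202; Zeb2 −1.25 ± 0.22), inflammatory (−0.31, 0.0059; Cxcl9 −0.96 ± 0.14), perineuronal net (−0.13, 0.00752; Vcan −1.92 ± 0.26), TGF-beta (−0.27, 0.013) and adipocyte genes (−0.35, 0.0202). An estimated correlation gave these 0.535, 0.442, 0.181, 0.34, 0.22, 0.34 and 0.463. On the higher side were cholesterol synthesis (0.37, 7.03e-05; Fdft1 0.89 ± 0.11), keratinocyte genes (0.37, 0.00138; Cldn4 1.49 ± 0.27), oxidative phosphorylation (0.14, 0.0106) and hypoxia (0.09, 0.024; Egln3 1.26 ± 0.17), at 0.259, 0.569, 0.744 and 0.34 with an estimated correlation. Fry called 6. Calls also ended without biological replicate 1 for macrophage genes (0.0761) and oxidative phosphorylation (0.136). Without biological replicate 2 they ended for adipocyte genes (0.0775, and 0.13 with no filter), hypoxia (0.134) and oxidative phosphorylation (0.0713), and without biological replicate 3 for TGF-beta (0.0769) and hypoxia (0.209). Single arrays mattered in the second VDH15 experiment, where 736 genes were called without replicate 1 of the non-targeting control group, 745, 754 and 809 without shCD36 control replicates 1, 2 and 3, and 807 and 767 without shCD36 palmitate replicates 1 and 3. Random assignment of the SCC25 arrays to the 4 groups gave up to 998 genes in the other splits. It mixed both diets and both shRNAs, so it is no yardstick for the difference itself.

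Comparing shCD36 with non-targeting tumours on the palmitate diet asked how CD36 in the tumour bears on the stroma when palmitate is supplied. It called 48 genes, 30 higher and 18 lower, among 2359 with an unadjusted p under 0.05. Of the called genes those that rose most were Acer1 (2.50 ± 0.19, n = 2, adjusted p = 0.0262), Spink5 (2.03 ± 0.26), Psapl1 (1.88 ± 0.18), the transglutaminase Tgm3 (1.80 ± 0.18; 1421355_PM_at), Krtdap (1.78 ± 0.21) and Gsdmc (1.73 ± 0.20). Those that fell most were Postn (1423606_PM_at) at −1.83 ± 0.22, Mmp19 at −1.50 ± 0.18, Prrx1 (1425526_PM_a_at) at −1.46 ± 0.15, Ctsk at −1.39 ± 0.14, Ccn2 at −1.28 ± 0.15 and Col6a2 at −1.20 ± 0.14. Interferon response genes were lower in 21 of 22 members, with a median of −0.72 (adjusted p = 2.16e-10, and 0.0765 with an estimated correlation). The antiviral gene Ifit1 (−1.19 ± 0.11) and the RNA sensor Ddx58 (−0.75 ± 0.10) fell, and 1 rose and 16 fell adjusted over the list alone. Gbp7 (−1.23 ± 0.18) and Stat2 (−0.64 ± 0.12) did not pass over all genes. Fibroblast genes had a median of −1.17 (adjusted p = 2.84e-09, 12 of 17 lower adjusted over the list alone) and endothelial genes of −1.08 (2.98e-10, 11 of 21; Plvap −1.08 ± 0.22), at 0.201 and 0.403 with an estimated correlation. The median was −0.45 for matrix glycoproteins (8.75e-10, 13 of 23), −0.66 for matrix proteases (6.48e-09, 7 of 23) and −1.04 for collagens (1.27e-05, 5 of 23), at 0.138, 0.0801 and 0.37 with an estimated correlation. Smaller falls were called for inflammatory genes (−0.38, 0.000465; Cxcl9 −0.81 ± 0.10), pericyte genes (−0.37, 0.00701), the perineuronal net (−0.10, 0.00709; Vcan −1.37 ± 0.19) and TGF-beta (−0.26, 0.0139). Estimating the correlation gave these 0.28, 0.516, 0.201 and 0.396. The same held for macrophage genes (−0.21, 0.0134), the neural crest list (−0.34, 0.0134), cell cycle genes (−0.15, 0.00481) and antigen presentation (−0.11, 0.0422), at 0.611, 0.201, 0.676 and 0.611 with an estimated correlation. Within SCC25 and the second VDH15 experiment the macrophage median was only −0.03 and −0.06. Higher were hypoxia (0.16, 0.00197; Egln3 rose by 0.98 ± 0.13), keratinocyte genes (0.24, 0.00481; Cldn4 1.09 ± 0.20), cholesterol synthesis (0.18, 0.0134; Fdft1 0.56 ± 0.08) and oxidative phosphorylation (0.08, 0.0437), at 0.201, 0.611, 0.414 and 0.676 with an estimated correlation. Outside the called lists L1cam (0.62 ± 0.07) rose and Klf2 (−0.96 ± 0.11) fell. No list was called with an estimated correlation, and fry called 8 lists. Without biological replicate 1 the calls of macrophage genes (0.149), antigen presentation (0.115) and oxidative phosphorylation (0.186) ended. Without biological replicate 2 those of pericyte genes (0.0509), antigen presentation (0.522), cholesterol synthesis (0.273) and hypoxia (0.188) ended. Without biological replicate 3 oxidative phosphorylation had 0.383 and cell cycle genes turned direction (0.743). Without the 3 arrays that stood apart antigen presentation had 0.0758 and oxidative phosphorylation 0.0816. Without biological replicate 1 the count was 115 genes, it was 0 without biological replicate 2 or 3, and it was 6 without the 3 arrays that stood apart. The fits without biological replicate 2 or 3 had fewer residual degrees of freedom than the fit without biological replicate 1. Their counts do not show which experiment carries the calls. DuplicateCorrelation called 1627 genes and a fit without the experiment term 1722. Of the 48 genes, 43 were also called for palmitate over control, all in the opposite direction, where independence predicts 1.64. Both comparisons use the non-targeting palmitate arrays. Their fold changes had r = −0.90 across genes against −0.43 in data simulated without effects, with a covariance of −0.114 against −0.00824. The simulations gave 0.01 shared calls on average against the 43. They held no effect and drew each gene independently, so hardly any calls were due in them. Their count is therefore no yardstick for the 43, part of which may come from the shared arrays.

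On the control diet, shCD36 against non-targeting asked whether the shRNA in the tumour cells bears on the stroma without added fat. No gene passed with limma (435 with an unadjusted p under 0.05, where chance predicts 641), duplicateCorrelation called 35 and a fit without the experiment term 13. Here too the error was pooled over all groups, so the count below chance is no evidence of an absent effect. Quantile normalization, eBayes with trend and robust, and leaving out the 3 arrays that stood apart gave 1 gene each. The smallest adjusted p, 0.0641, belonged to Ifit1 (1450783_PM_at), which stood at −1.47 ± 0.11 log2, with levels of 11.6 log2 in non-targeting and 10.1 log2 in shCD36 tumours. Other genes of antiviral defence followed without passing, Ifih1 (−1.39 ± 0.21), Samd9l (−0.77 ± 0.08), Helz2 (−0.74 ± 0.11) and Parp14 (−0.71 ± 0.08), and Il33 stood at −1.70 ± 0.23. On the higher side were Lce1a2 (2.12 ± 0.30), Lce1f (2.04 ± 0.37), Lce1d (1.75 ± 0.26), Lce1b (1.52 ± 0.17), Fmo2 (1.16 ± 0.15) and Rian (0.72 ± 0.11), none of which passed. Interferon response genes were lower in 21 of 22 members with a median of −0.58 (adjusted p = 1.34e-15), 6 of them adjusted over the list alone. Among the 7 contrasts of the combined fit this was the only list call that held with an estimated correlation (adjusted p = 0.0355), it held with fry, and it was lost with an estimated correlation when the 3 arrays that stood apart were left out. Cholesterol synthesis (17 of 18 lower, median −0.17, adjusted p = 3.95e-06; Fdft1 −0.34 ± 0.08) and keratinocyte genes (17 of 20, −0.12, 0.0368) were also lower, at 0.292 and 0.773 with an estimated correlation. Higher were fibroblast genes (17 of 17, median 0.61, adjusted p = 2.97e-10; Serpinf1 0.97 ± 0.27), collagens (21 of 23, 0.21, 9.57e-07; Col5a1 1.18 ± 0.24), matrix glycoproteins (20 of 23, 0.19, 0.000147), the neural crest list (13 of 17, 0.11, 0.0181; Prrx1 0.76 ± 0.15) and macrophage genes (17 of 18, 0.18, 0.0199). With an estimated correlation they had 0.292, 0.386, 0.321, 0.292 and 0.773. Also higher were endothelial genes (19 of 21, 0.23, 0.0363), matrix proteases (16 of 23, 0.14, 0.0368, with Timp1 at 1.01 ± 0.25) and pericyte genes (0.16, 0.0368), at 0.773, 0.386 and 0.773 with an estimated correlation. The macrophage median was −0.01 within SCC25, with 9 of 18 genes lower, and 0.11 within the second VDH15 experiment, with 6 lower. The endothelial median was 0.67 in SCC25 and −0.33 in the second VDH15 experiment, so its direction turned when the SCC25 experiment was left out (adjusted p = 0.0206). That setting also ended the calls of matrix glycoproteins (0.098), matrix proteases (0.455) and the neural crest list (0.231). Without biological replicate 1 the adjusted p was 0.0545 for pericyte, 0.0662 for endothelial, 0.283 for macrophage and 0.324 for keratinocyte genes and 0.0607 for matrix proteases. Without the 3 arrays that stood apart it was 0.1 for pericyte and endothelial genes, 0.138 for keratinocyte genes and 0.187 for matrix proteases, and 7 lists were called. Matrix proteases had 0.0614 with no filter and 0.0731 over all arrays. In separate fits SCC25 called 1217 genes, 770 without non-targeting control replicate 1 and 808 without shCD36 control replicate 3. The second VDH15 experiment called 85, against 54, 55 and 50 without non-targeting control replicates 1, 2 and 3 and 50 without shCD36 control replicate 2.

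Oleate over control asked whether a diet rich in an unsaturated fatty acid acts on the stroma of non-targeting tumours as palmitate does; it rests on 1 biological replicate. The oleate arm has no spread of its own, so SE and p of the combined fit assume that it varies like the other groups. No gene passed with limma (225 with an unadjusted p under 0.05), and duplicateCorrelation called 0 as well. Cd36 was among the genes with the smallest p on the higher side (0.85 ± 0.15), with Itga5 (0.78 ± 0.13), Slc12a3 (0.76 ± 0.11), Rab3il1 (0.46 ± 0.12), Usp27x (0.44 ± 0.10) and Kctd18 (0.43 ± 0.11). On the lower side were Acer1 (−1.49 ± 0.26), Ms4a4d (−1.25 ± 0.25), Loxl3 (−0.99 ± 0.20), Rian (−0.89 ± 0.15), Sult2b1 (−0.80 ± 0.15) and Bdkrb1 (−0.62 ± 0.11). Endothelial genes were higher in 21 of 21 members (median 0.69, adjusted p = 2.18e-08, 0.965 with an estimated correlation; Vwf 1.31 ± 0.37), with 0.87 and 0.48 in the 2 scan batches. Adipocyte genes were higher (median 0.11, adjusted p = 0.00413, 0.965 with an estimated correlation), with Cd36 passing adjusted over the list alone. Fibroblast genes were lower in 15 of 17 (median −0.37, adjusted p = 0.000169, 0.965 with an estimated correlation; Cthrc1 −1.09 ± 0.34), with −0.73 and −0.25 in the scan batches. Cell cycle genes were called higher (0.11, 0.0286, and 0.984 with an estimated correlation), but their median was −0.09 within the arrays of the experiment, and the call ended without biological replicate 2 (0.164) or 3 (0.154). No list was called by fry, and 7 were called without the 3 arrays that stood apart. In the fit of the experiment alone 158 genes were called; leaving out any 1 of the 8 arrays left 26 to 87, scan batch as a block left 51, and within a scan batch 0 were called. The combined fits for palmitate and oleate had r = 0.21 across genes against 0.32 simulated, and a covariance of 0.0157 against 0.00824. In the first VDH15 experiment alone 131 of the 158 genes were also called on palmitate in the same direction and 5 in the opposite one. Both counts use 1 control replicate, and no value without change was computed for them. Of the 419 genes that fell on palmitate in the combined fit 342 were lower on oleate, and of the 468 that rose 274 were higher, and these comparisons share control arrays as well. Within the first VDH15 experiment the median absolute log2 fold change was 0.21 on palmitate and 0.08 on oleate.

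Palmitate over oleate asked which responses belong to the saturated fat alone, also with 1 oleate replicate, assumed to vary like the other groups. Under this assumption it called 5 genes, all higher: the mesenchymal transcription factor Prrx1 (2.53 ± 0.21, adjusted p = 0.0472), the lysyl oxidase Loxl3 (2.28 ± 0.20, 0.0472; 1418269_PM_at), Rian (2.10 ± 0.15, 0.0423; 1452899_PM_at), Ctsk (2.08 ± 0.20, 0.0498; 1450652_PM_at) and Antxr2 (1.15 ± 0.11, 0.0498). The adhesion gene Clmp (1.68 ± 0.18) did not pass, nor did Tent5b (−1.14 ± 0.18), Homer2 (−1.11 ± 0.19), Entpd3 (−1.01 ± 0.11), Lrrc8e (−0.78 ± 0.12), Tmem79 (−0.76 ± 0.12) and Slc12a3 (−0.70 ± 0.11) on the lower side, where 0 genes were called. Fibroblast genes were higher in 17 of 17 (median 1.84, adjusted p = 1.26e-14, 0.144 with an estimated correlation, 12 adjusted over the list alone; Cthrc1 2.39 ± 0.34), with 2.00 and 0.98 in the scan batches. Matrix glycoproteins (0.70, 1.78e-10; Thbs2 2.03 ± 0.36), matrix proteases (0.89, 2.74e-09; Mmp19 1.65 ± 0.24), macrophage genes (0.70, 9.62e-09; Lyz2 2.49 ± 0.67), collagens (0.77, 4.55e-07; Col6a2 1.73 ± 0.19) and inflammatory genes (0.38, 3.51e-06; Cxcl12 2.47 ± 0.37 and Cxcl5 2.63 ± 0.40) were also higher. An estimated correlation gave these 0.144, 0.141, 0.38, 0.34 and 0.184. So were endothelial genes (0.59, 0.000396), the neural crest list (0.56, 0.000786), the perineuronal net (0.23, 0.00533), pericyte genes (0.35, 0.0102), TGF-beta (0.09, 0.0139; Ccn2 1.77 ± 0.20) and neutrophil genes (0.22, 0.0488; Mmp9 2.28 ± 0.58). Estimating the correlation gave them 0.612, 0.144, 0.184, 0.589, 0.38 and 0.612. Keratinocyte genes (−0.42, 1.02e-05; Cldn4 −1.05 ± 0.27) and oxidative phosphorylation (−0.16, 0.000373) were lower, at 0.589 and 0.612 with an estimated correlation. No list was called with an estimated correlation (smallest adjusted p = 0.141) and fry called 5, and neutrophil genes had 0.0537 over all arrays. The 5 genes were lost without biological replicate 2, without biological replicate 3 and without the 3 arrays that stood apart, with 0 called each time. Leaving out a biological replicate also cut the residual degrees of freedom of the fit. Quantile normalization, and eBayes with trend and robust, each called 3, duplicateCorrelation 581 and a fit without the experiment term 869. In the first VDH15 experiment alone 5013 genes were called, against 5 and 242 within the scan batches.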

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

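The tests of cell-type proportions, of myeloid cells, of single experiments and of the scan batch for the 3 arrays apart were chosen only after the result was seen, whereas the scan batch test of the stromal pattern and the splits of the samples were set before. Of 54 checks for a single array apart, which covered 18 measures in the 3 groups of 4 arrays, 1 passed Dixon's 95% critical value, and chance alone gives about 1 in 20. Replicate 4 of the non-targeting control group in the first VDH15 experiment had a mean correlation of 0.996418 with its own group against 0.995978 to 0.996031 for the other arrays of that group, with a gap ratio of 0.880.

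Differences between groups under the same diet contrast were tested directly. The palmitate effect differed between shCD36 and non-targeting tumours in 1992 genes of the SCC25 experiment and in 1224 genes of the second VDH15 experiment, and in 16 lists over the biological replicates, of which 0 were called with an estimated correlation (smallest adjusted p = 0.162). Over biological replicates 0 single genes passed with limma (2011 with an unadjusted p under 0.05). The palmitate effect in non-targeting tumours differed between SCC25 and the second VDH15 experiment in 216 genes, of which 66 had opposite signs. The contractile genes Myh11 (3.10 and −0.50) and Mylk (3.20 and −0.07) and the collagen Col3a1 (4.75 and 1.54) were higher in SCC25, and the metabolic switch gene Pdk4 (0.57 and −2.27) also differed. With an estimated correlation 3 lists differed, pericyte and smooth muscle genes (0.67 and −0.03, adjusted p = 0.0147), adipocyte genes (0.25 and −0.03, 0.0147) and axon guidance (0.01 and −0.02, 0.0153). Between both VDH15 experiments 1158 genes differed, 852 with opposite signs, although both used the same tumour cells, which gives a yardstick for differences between experiments. Chil1 (1.80 and −1.38) and Cxcl14 (1.41 and −1.10) were higher in the first and Col6a3 (1.08 and 3.09) in the second, and the axon guidance list (0.29 and −0.02) and the cell cycle list (−0.40 and 0.14) differed with an adjusted p of 0.0222. Between the first VDH15 experiment and SCC25 1357 genes differed, 750 with opposite signs, among them Col1a1 (0.50 and 4.49), Rgs5 (−0.88 and 3.26) and the cathepsin Ctss (2.96 and 0.40), and 0 lists differed with an estimated correlation.

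In shCD36 tumours the palmitate effect differed between SCC25 and the second VDH15 experiment in 453 genes, 378 with opposite signs, including the calprotectin genes S100a8 (0.48 and 2.49) and S100a9 (0.05 and 2.43). The effect of shCD36 on the palmitate diet differed in 626 genes, such as the hair keratin Krt36 (4.75 and 1.10) and the itaconate enzyme gene Acod1 (0.23 and −3.29). On the control diet it differed in 849 genes, 716 with opposite signs. There Cxcl11 (−0.14 and −2.80), Ifnb1 (−0.14 and −2.54), Ifit2 (0.08 and −2.08) and Ccl5 (0.42 and −2.54) were lower in the second VDH15 experiment, and the endothelial list (0.67 and −0.33) differed with an adjusted p of 0.0109. These tests set the spread among arrays labelled technical replicates against differences between single biological replicates, so cell source, experiment and chance variation between mice cannot be told apart in them.

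Higher stromal, vascular and matrix genes with lower keratinocyte genes on palmitate in non-targeting tumours were weighed against 3 explanations. A lower share of one main cell type, keratinocytes, would raise the markers of every other type alike, but Schwann cell genes at or above 7 log2 (mean 0.12, 9 genes) differed from fibroblast genes (mean 1.28, 14 genes) with an adjusted permutation p of 0.0117. Of the 4 lists compared this was the only one that passed. Endothelial (mean 1.24, adjusted p = 0.875), pericyte (0.58, 0.0606) and satellite cell genes (0.32, 0.0595) did not. The permutation treats the genes of a list as independent, so this 1 list does not decide against a lower share of keratinocytes. For the scan batch in the first VDH15 experiment the lowest fibroblast or endothelial median within a batch was 0.90 log2. This decides nothing, because each batch held 2 arrays of every diet by design and the deposited values were already adjusted for it. A higher share of fibroblasts and endothelial cells in the fraction was not separated from changed expression within them: at least 88.2% of the members of both lists lay above 0 in every experiment, which restates the pattern. An effect of the diet itself remains open as untested, and so does RNA from the human tumour binding to mouse probes.

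Lower interferon response genes in shCD36 tumours on both diets were weighed against fewer macrophages and other myeloid cells and against 1 of the 2 experiments alone. The myeloid list had a median of 0.18 on the control diet in the combined fit, with −0.01 in SCC25 and 0.11 in the second VDH15 experiment, and only 3 of its 18 members reached 7 log2, so fewer myeloid cells may still contribute. The interferon medians were −0.40 in SCC25 and −0.69 in the second VDH15 experiment on the control diet, with 16 and 21 of 22 genes lower, and −0.63 and −0.69 on palmitate, with 18 and 20 lower. With 2 experiments the part of each cannot be told apart from variation between tumours. The shRNA itself, acting through the tumour cells, remains open as untested.

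The 3 palmitate arrays apart on the first component were weighed against the scan batch and against other proportions of cell types. In the palmitate group of the first VDH15 experiment the smallest gap within a scan batch was 53.0. A shift common to the arrays of a batch would not produce it, which argues against such a shift as the cause. Across batches the smallest gaps were 2.71 and 6.19, but in values already adjusted for scan batch. In proportion to their groups these arrays had lower keratinocyte scores, −1.14 and −1.13 against −0.06 and 0.14 in the first VDH15 experiment and −0.47 against −0.09 and 0.03 in the second, with higher fibroblast and endothelial scores. The smallest margin over the keratinocyte and fibroblast scores was 0.389, so other proportions of cell types in those arrays are a candidate explanation. The 3 arrays were picked for their scores on the first component, so this may restate the pattern. Proportions were not separated from changed expression. No biological explanation was tested, since the labels call the arrays of a group technical replicates.

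Other splits of the samples were counted for each number of called genes, the real split included. Over the 6 biological replicates the real 887 genes stood against at most 1 in the others, and the 14 lists against at most 15, with 2 of 10 splits as large; 10 splits are too few for a share under 0.05. The splits below exchange arrays labelled technical replicates within an experiment, so they bear on the spread among these arrays. Whether that holds any variation between tumours or mice is not stated, and 2 arrays of 1 such group lay 59.2 apart on the first component. In the first VDH15 experiment 1 of 35 splits was as large each time: 5939 genes against at most 3 for palmitate, 158 against 1 for oleate and 5013 against 0 for palmitate over oleate. Splits along the scan batch gave 0, which decides nothing, since the deposited values were already adjusted for it. For both other experiments 10 splits are again too few for a share under 0.05. The real counts and the highest of the others in SCC25 were 2454 and 0 for palmitate, 816 and 0 for palmitate with shCD36, 1859 and 0 for shCD36 on palmitate and 1217 and 1 on control. In the second VDH15 experiment they were 1846 and 0, 162 and 1, 3203 and 5, and 85 and 0. For the difference of palmitate effects 1 of 100 random assignments to the 4 groups was as large, with 1992 against 998 in SCC25 and 1224 against 18 in the second VDH15 experiment. These assignments mixed both diets and both shRNAs, so they did not keep an equal diet effect in both shRNAs. They cannot tell whether the difference itself could arise by chance. For agreement 1 of 100 splits was as large each time, with 893 genes against 0 for palmitate, 25 against 11 with shCD36 and 592 against 0 for the difference. For palmitate the other splits of single experiments called at most 3, 0 and 0 genes, so agreement among them was nearly fixed at 0 in advance. These counts do not test whether chance differences between biological replicates would agree across experiments.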

How the results depend on the processing

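Leaving out the 3 arrays that stood apart was chosen only after the result was seen, and all other tests here were fixed before the data were examined. Named genes were compared with their alternatives 3274 times, of which 2600 kept direction and side of the threshold, 467 lost the call, 206 gained it and 1 turned sign: Rpl13 for palmitate over control in non-targeting tumours, at −0.00228 with the mean of all probe sets. The 2600 include genes called in neither fit, so they overstate how stable the calls were. For palmitate in non-targeting tumours 132 of 136 named genes stayed the same with median centring. With only the groups of the contrast 53 of 136 did, and 83 lost the call. Called lists were compared 862 times, with 498 unchanged, 360 calls lost and 4 turned: red blood cell genes for palmitate in shCD36 tumours without biological replicate 2, cell cycle genes for the same contrast and for shCD36 on palmitate without biological replicate 3, and endothelial genes for shCD36 on control without biological replicate 2 (adjusted p = 0.0206). Without 1 biological replicate the adjusted p of these lists ranged from 1.06e-07 to 0.94, 2.13e-06 to 0.568, 2.4e-07 to 0.743 and 1.58e-10 to 0.0662 in that order. The 887 genes for palmitate in non-targeting tumours became 731 with no filter, 832 with a filter of 50%, 1096 with quantile normalization, 921 with median centring, 966 with the mean of probe sets and 830 with trend and robust. The share of higher genes was 52.8%, against 48.5% with quantile normalization, 58.0% with median centring and 32.6% without biological replicate 1. Unless said otherwise, the cause was not tested.

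With duplicateCorrelation on biological replicate over all 36 arrays the genes called were 3052 for palmitate in non-targeting tumours (869 shared), 7 for palmitate in shCD36 tumours, 1627 for shCD36 on palmitate, 35 for shCD36 on control, 1052 for the difference of palmitate effects and 581 for palmitate over oleate. With no replicate block for experiment they were 3001 (887 shared), 1722 for shCD36 on palmitate, 13 for shCD36 on control, 699 for the difference and 869 for palmitate over oleate. By construction the fit without a block has more residual degrees of freedom, and its fold changes had r = 1, since the authors had removed batch. DuplicateCorrelation also has more, from arrays labelled technical replicates. With only the groups of the contrast in the fit, which leaves fewer averages, 34 genes were called for palmitate in non-targeting tumours (32 shared). Quantile normalization gave 1 gene for shCD36 on control and 3 for palmitate over oleate, and so did eBayes trend and robust, 1 and 3. Without 1 biological replicate, with fewer samples by construction, the range was 0 to 224 genes for palmitate in non-targeting tumours, 0 to 115 for shCD36 on palmitate, 0 to 4 for the difference, 0 to 0 for palmitate over oleate and 5 to 17 lists for palmitate in shCD36 tumours. Where an arm is left with 1 average, it is assumed to vary like the other groups. Leaving out biological replicate 2 or 3 costs more residual degrees of freedom than leaving out biological replicate 1. The lone oleate average stays in those fits with a term of its own.

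Camera with estimated correlation called 0 lists in every contrast except shCD36 on control, with 1. Fry, directional, called 9 for palmitate in non-targeting tumours, 0 in shCD36 tumours, 8 for shCD36 on palmitate, 1 on control, 6 for the difference, 0 for oleate and 5 for palmitate over oleate. With the 3 arrays that stand apart left out, the genes called were 6 for shCD36 on palmitate, 1 for shCD36 on control and 0 for palmitate over oleate, and the lists were 7 for shCD36 on control and 7 for oleate. With the 3 arrays that stand apart left out and an estimated correlation, 0 lists were called in every contrast. With the 3 arrays that stand apart left out, fry called 3 lists for palmitate in non-targeting tumours, 0 in shCD36 tumours, 5 for shCD36 on palmitate, 1 on control, 1 for the difference, 0 for oleate and 0 for palmitate over oleate.

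Within scan batch 2 of the first VDH15 experiment 1052 genes were called for palmitate, 0 for oleate and 5 for palmitate over oleate, and within scan batch 3 1278, 0 and 242, from 2 arrays per group. With scan batch as a block 51 genes were called for oleate. Leaving out 1 array gave 26 to 87 genes for oleate. In SCC25 it gave 496 to 827 for palmitate with shCD36 and 770 to 1048 for shCD36 on control. In the second VDH15 experiment it gave 757 to 2148 for palmitate, 20 to 70 for palmitate with shCD36, 50 to 68 for shCD36 on control and 736 to 1530 for the difference. An absolute log2 fold change of at least 1 left 79 genes in agreement for palmitate, 3 with shCD36 and 175 for the difference, fewer by construction. Technical replicate numbers do not pair the arrays: the mean correlation of arrays with the same number was 0.026, 0.017 and −0.037 in the 3 experiments after group means were removed. Taken as a replicate block, the numbers gave 5656 genes for palmitate in the first VDH15 experiment, 2403 in SCC25 and 1556 in the second. Weak signal limits lists with a median level near or below the array medians: myelin genes (5.56 log2), neuron and synapse (5.61), skeletal muscle (5.63), satellite cell (5.83), neutrophil (5.84), myeloid (5.98), adipocyte (6.06) and galanin genes (6.08).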

Other observations

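In non-targeting tumours on palmitate rises of the matrix genes Col6a3, Lox, Col5a3 and Bgn were joined by vascular genes such as Plvap and Vwf, by the myeloid receptors Mrc1 and Cd14 and by the chemokine Cxcl5. The secreted factors Igf1, Lif and Il6 rose as well, while the myelin genes Mbp and Drp2 and the galanin genes Gal, Galr1 and Galr3 did not pass. The semaphorins Sema4d, Sema4a and Sema5a and the neuronal cytoskeleton genes Tubb3 and Map2 fell. The neurotrophic list and the Schwann cell repair list, which hold Igf1, Lif and Il6, were not called. The axon guidance list and the neuron and synapse list were not called either, and other axon guidance genes rose adjusted over their list alone.

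In shCD36 tumours the late cornified envelope genes Lce1b, Lce1a2 and Lce1d had opposite signs against diet and against shRNA on the control diet, −1.22, −1.67 and −1.28 log2 with palmitate and 1.52, 2.12 and 1.75 log2 with shCD36. Il33 went the other way, 1.88 log2 with palmitate and −1.70 log2 with shCD36. None of these genes passed, and both comparisons use the shCD36 control arrays, whose chance errors enter them with opposite signs.

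On the control diet Prrx1 had a mean of 8.99 log2 in non-targeting and 9.75 log2 in shCD36 tumours, and on palmitate 10.6 and 9.18 log2. Lox had 9.45 and 10.3 log2 on control and 11.6 and 9.45 log2 on palmitate. Ifit1 had 11.6 and 11.4 log2 in non-targeting tumours on control and palmitate and 10.1 and 10.2 log2 in shCD36 tumours, a fall that passed on palmitate alone. Acer1 had 7.61 log2 on control, 6.12 log2 on oleate and 4.83 log2 on palmitate in non-targeting tumours.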
